A study of Homo sapiens with 4 samples.

How the data were processed

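H4K20me1 was measured by CUT&Tag in 4 libraries of Kasumi-1 cells, 2 labelled as non-targeting control and 2 as SETD8 knockout. Nothing in the labels says that libraries of a group came from separate cultures. Per the submitters' processing notes, cutadapt, Bowtie2, DESeq and genome build hg38 were used. Their versions and order, the peak caller, the treatment of duplicates and the number of libraries behind each value are not given in the sources used here. No control library without antibody and no spiked-in DNA was used here, so a uniform loss of the mark over the genome cannot show in these values.

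The data were 1 table of the whole series, with 25514 peaks of 271 to 5984 bp (median 1097) that cover 31.4 Mb. The values deposited by the authors are log2 scaled reads per peak in each of the 2 groups, the log2 fold change between them, an unadjusted p-value and an adjusted p-value. The file names its value columns only by number, so their meaning was settled from the values: in all 25514 peaks the fold column equals the first-listed minus the second-listed column within 0.01. Every low log2 value in the authors' columns (from 1.5 to 5.5, 5676 values in the first-listed and 5557 in the second-listed column) equals log2 of a whole number of reads plus 1 constant per column, within 0.0051. The constant was 0 in the first-listed and −0.057 in the second-listed column. Each column thus holds the reads of 1 library, or of libraries merged before counting, times 1 factor. In simulated means of 2 libraries with different factors, 28.7% of values met this rule. The adjusted p-values imply between 115 and 226 more tested peaks than the table lists, and those peaks were not analysed here.

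With 1 column per group no test of differences was made here, and p-values are those of the authors' deposited table. Design choices fixed before the data were examined had foreseen this case. Recovered whole reads gave the depth of each peak (quartiles 45 and 129 in the first-listed, 47 and 124 in the second-listed column) and an exact Clopper-Pearson 95% interval for each log2 fold change, which covers counting error only. Read numbers of 2 to 7, found in 237 peaks of the first-listed and 222 of the second-listed column, were even in 75.5% and 86.9% of cases, and those of 32 to 63 in 51.2% and 50.9%. Whether both ends of a fragment were counted is thus not settled, and where they were, such intervals are too narrow. In 648 peaks both columns stood at their lowest step.

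A peak in a promoter (up to 3 kb), untranslated region, exon or intron was given to a gene, by the host gene that the annotation names for exons and introns and otherwise by the nearest gene. Of 10205 exon and intron peaks, 1051 named no host gene number and 1386 named a host other than the nearest gene. Symbols and gene lengths came from the RefSeq table of GRCh38.p14, in which 10031 of 10065 nearest genes were found. The genes named were the 10 lowest and 10 highest log2 fold changes among peaks at or above the median mean signal, 1 peak per gene, without uncharacterized, long intergenic, small RNA and antisense genes, plus KMT5A and up to 2 genes per list. The rule was to apply to peaks past the threshold, and since none passed it was used by size alone, as it provides. A gene that the rule names is not reported here.

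For 23 gene lists fixed before the data were examined, the median over genes of the mean peak log2 fold change was set against 10000 random lists of the same size matched on decile of mean signal and on number of peaks (seed 20240). Lists needed at least 5 measured genes. The percentile describes these columns and is no test of the conditions. The share of genes with a peak was set against lists matched on decile of gene length. Odds ratios for classes and chromosomes have 95% intervals and no p-value. Regional medians used windows of 5 Mb, and intervals for regions came from 1000 resamplings of such windows.

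On simulated data drawn from the reads of this comparison, 3 of 100 unshifted lists of 30 genes out of 8743 fell outside the random range, and a shift of 0.2 was found in 97.0% of lists and one of 0.4 in 100%. The simulated peaks varied independently, with reads drawn in pairs. The real log2 fold changes had a standard deviation of 0.442, against 0.396 expected for such pairs. Peaks of a gene could also move together, as the 36 of TRIO did. The shares found are thus likely too high for the real lists. Smaller lists also had wide random ranges, −0.31 to 0.41 for the 7 measured liver markers and −0.21 to 0.34 for the 10 myeloid markers. A shift of 0.2 can stay inside such ranges, so the shares found for 30 genes do not apply to small lists. A simulated shift of −0.3 over 2124 peaks came back as −0.30. Alternatives covered thresholds, signal filters, peak-to-gene assignment, promoter reach and, chosen after seeing the data, scaling to reads in peaks, no scaling, and leaving out lowest-step peaks or 3 chromosome segments. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.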

Results

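H4K20me1, the monomethylated form of lysine 20 on histone H4, was profiled by CUT&Tag in Kasumi-1 cells, an acute myeloid leukemia line that carries the t(8;21) translocation. In CUT&Tag an antibody directs the Tn5 transposase to chromatin that bears the mark, so that the cut fragments can be sequenced. The series held 4 libraries of 100000 cells each, 2 from cells with a non-targeting guide (control) and 2 from cells in which SETD8 was knocked out with CRISPR/Cas9. SETD8, now named KMT5A, is the enzyme that places this methyl group, and the comparison asked where the mark differed after its loss. The deposited table listed 25514 peaks with 1 value per group, not per library. Recovered reads in peaks numbered 2791207 in the first-listed group and 2682916 in the second-listed group, and the median peak held 72 reads in each. No header states which group comes first. The name of the deposited comparison puts treated before control, which would make the knockout the first-listed group, but values are given below as first-listed and second-listed. There was no replicate check for any difference, and peak coordinates are those of hg38.

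KMT5A itself held 3 peaks on chromosome 12, of which 1 lay in the promoter (123389698 to 123391291) and 2 in intron 5 of 8 (123398345 to 123399648 and 123402568 to 123402852). Their log2 fold changes, first-listed minus second-listed, were 0.32, 0.28 and 0.15. Summed over the 3 peaks, 489 and 422 reads gave a log2 ratio of 0.27 (exact 95% interval 0.08 to 0.46, counting error only). With the columns scaled to equal reads in peaks, a choice made after seeing the data, the ratio was 0.16 (−0.04 to 0.35). The smallest unadjusted p among these peaks was 0.421 in the authors' deposited table. The mark over the locus measures neither the edit nor the amount of the enzyme, so it checks nothing about the labels.

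Among gene peaks of at least median signal, the widest gap between the groups was in exon 4 of CRYBG1 (chromosome 6, 106519133 to 106521259), with 169 reads in the first-listed and 44 in the second-listed group, a log2 fold change of 2.00 (exact 95% interval 1.51 to 2.51). FAM107B followed at its promoter (1.66, 1.27 to 2.06), and an intron of RANBP9 gave 1.64 (1.13 to 2.18). The promoter of CD34, a surface marker of hematopoietic stem and progenitor cells, gave 1.42 (0.89 to 1.97) at chromosome 1, 207898587 to 207899752. At the other end stood an intron of SYT1, the calcium sensor of synaptic vesicles, at −1.36 (−1.88 to −0.86).

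None of these peaks passed the test. In the authors' deposited table, which came from DESeq per the submitters' processing notes, 0 of 25514 peaks had an adjusted p under 0.05, and 1292 had an unadjusted p under 0.05, of which 860 were higher and 432 lower in the first-listed group. A uniform spread of p-values would put 1275.7 peaks under that limit. The columns hold no separate libraries, so the spread within a group that these p-values assume cannot be checked. The counts of 0 and 1292 peaks thus cannot decide whether the mark differed between the groups. The smallest adjusted p in the authors' deposited table was 0.0704, for CRYBG1 (unadjusted p 2.74e-06). With no peak past the threshold, the genes named here were ranked by size of difference alone.

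Among the 10 highest genes, 7 had their peak in an intron. ANKRD28 (1.5), GAB2 (1.49), which encodes a docking protein of receptor signalling, CDK17 (1.49), AFDN (1.38), TRIO (1.37) and ZNRF3 (1.35), a ubiquitin ligase that turns over Wnt receptors, completed the group. TRIO was the most deeply covered of them, with 449 and 181 reads in its peak at chromosome 5, 14325232 to 14326686, in intron 9 of 56 (interval 1.12 to 1.62). The 10 lowest included introns of CEP72 (−1.34), RBFOX3 (−1.15) and CSMD1 (−1.13) beside SYT1. Promoters of PDCL (−1.33), NR1D1 (−1.31), the circadian repressor REV-ERBα, GALK1 (−1.22), GAS2 (−1.17), GGA3 (−1.15) and RCCD1 (−1.13) made up the rest. PDCL, NR1D1, GALK1, GGA3 and RBFOX3 lie on parts of chromosomes 9 and 17 whose peaks had medians of −0.17 and −0.20.

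Over all 25514 peaks the median log2 fold change was 0.06, with quartiles of −0.19 and 0.32, and 97.54% of peaks lay within a log2 fold change of 1 in either direction. The central 95% of peaks ran from −0.79 to 0.88. Peaks at or above the median mean signal had a median fold change of 0.12. A log2 fold change of 1 or more in size was listed for 627 peaks, of which 395 were higher and 232 lower in the first-listed group. The center of this distribution depends on the scaling between the columns. Scaling to equal reads in peaks, chosen after seeing the data, moved every fold change by −0.11, the median to −0.054 and the share of peaks below 0 from 40.9% to 55.3%. Among peaks of at least median signal, those with a difference of 1 or more then numbered 59 higher and 73 lower, in place of 135 and 32.

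**Figure D1:**
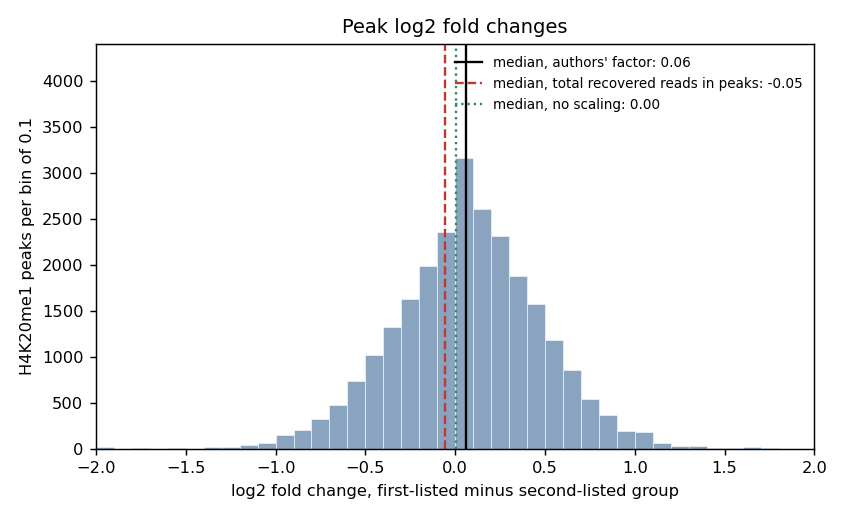
Histogram of the log2 fold change of H4K20me1 peaks (x axis, first-listed minus second-listed group; drawn from −2 to 2; y axis, peaks per bin of 0.1), with vertical lines at the median under the authors' factor (0.06), scaling to reads in peaks (−0.05) and no scaling (0.003). The quartiles lie at −0.19 and 0.32, and the 3 medians fall between them.

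Introns and promoters held most of the peaks. By the authors' annotation, 36.3% of peaks were intronic (Wilson 95% interval 35.8 to 36.9) and 34.3% lay in promoters of up to 3 kb (33.7 to 34.8). A further 22.8% were distal intergenic (22.3 to 23.3). Promoter peaks were also the deepest of these, with a median of 99.7 scaled reads in the first-listed group against 72.0 for introns and 48.8 for intergenic peaks. The median log2 fold change was 0.10 in introns and 0.09 in promoters, and −0.01 in distal intergenic peaks. The promoter median exceeded the intergenic median by 0.10 (95% bootstrap interval over peaks 0.08 to 0.11). This interval treats peaks as independent, so it is too narrow, and it holds no spread between libraries.

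Because 0 peaks passed the adjusted threshold, no test over classes was made, and the peaks with an unadjusted p under 0.05 in the authors' deposited table are described in its place. Introns held 48.7% of those higher in the first-listed group (odds ratio 1.70, interval 1.48 to 1.94) and 28.0% of those lower (0.68, 0.55 to 0.84). Distal intergenic peaks made up 10.9% of the higher (0.41, 0.33 to 0.51) and 40.05% of the lower (2.30, 1.90 to 2.80). Promoters held 33.0% of the higher (0.94, 0.82 to 1.09) and 26.9% of the lower (0.70, 0.57 to 0.87). Among peaks at or above the median signal, the promoter odds ratio was 0.64 (0.53 to 0.76) for higher and 0.84 (0.60 to 1.17) for lower peaks. Neighbouring peaks are not independent, so these intervals are too narrow.

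Genes of DNA replication and of the cell cycle had lower H4K20me1 in the first-listed group than matched genes. Under the naming rule, values for single genes of a list are those of their peak with the largest difference among peaks of at least median signal, and weaker peaks can differ by more. Other peaks of the same gene can also differ by less or go the other way, while list medians use the mean over a gene's peaks. In the replication list, 22 of 29 measured genes had a mean peak log2 fold change below 0 and 6 above, and the median was −0.19, at percentile 0.005 among 10000 random lists matched on signal and number of peaks (median of random lists 0.10). RRM2, a subunit of ribonucleotide reductase, stood at −0.80 and DTL, the adaptor that marks KMT5A for degradation in S phase, at −0.94. The mean over the 3 peaks of DTL was −0.35. In the list of cell cycle and mitosis, 26 of 39 genes were below 0 and 13 above, with a median of −0.12 (percentile 0.06), and its leading peaks were those of SMC4 (−0.87), a condensin subunit, and BIRC5 (−0.83), which encodes survivin. RRM2 and BIRC5 lie on parts of chromosomes 2 and 17 whose peaks had medians of −0.19 and −0.20. Genes of the DNA damage response were below 0 in 14 of 24 cases, with a median of −0.11 (percentile 1.07). FANCA gave −0.63 and WRN, a helicase, 0.59. The damage list lay inside the random range when peaks were assigned by nearest gene (−0.06) or limited to those at or above the median signal (−0.04).

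Markers of myeloid differentiation stood at the other end. Of 49 genes in this list 10 were measured, 9 of them above 0, and the median was 0.42 (percentile 99.4, median of random lists 0.09). With all peaks by nearest gene it was 0.27 over 15 genes, and fewer than 5 of its genes had peaks of at least median signal. EGR1 (0.55) and EGR2 (0.44), zinc-finger factors of the early growth response family, were its leading genes under the naming rule. Neuronal markers, included as genes of another cell type, had 15 of 17 members below 0 and a median of −0.21 (percentile 0.03), led by SYT1 and RBFOX3. Without the peaks on the short arm of chromosome 2, chromosome 9 from 40 Mb and chromosome 17 from 25 Mb, a choice made after seeing the data, the neuronal median was −0.12 (percentile 3.48), while replication (−0.18), cell cycle (−0.10), damage response (−0.08) and myeloid (0.44) genes stayed outside the random range.

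Nuclear genes of mitochondrial function lay within the range of random lists. The subunits of oxidative phosphorylation had 29 of 44 genes above 0 and a median of 0.09 (percentile 52.8), with NDUFS5 at 0.65 and ATP5PB at 0.61. NDUFV3 (0.68) and ATP5PO (−0.63) differed by as much in peaks below the median signal. Mitochondrial dynamics, biogenesis and mitophagy had 21 of 38 genes above 0 and a median of 0.12 (percentile 66.5). CHCHD6 gave 0.89 and POLG, the mitochondrial DNA polymerase, 0.79, while the means over their 11 and 2 peaks were 0.47 and 0.20. TFB1M gave −1.20 in a peak below the median signal. FH, the fumarase of the TCA cycle, gave 0.90 and MDH1, on the same part of chromosome 2 as RRM2, −0.77 in a list with a median of 0.09 (percentile 51.0). The mitochondrial ribosome had a median of 0.01 (percentile 21.0), with MRPL18 at −0.53 and MRPS18A at 0.32.

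The remaining lists also lay inside the random range. Targets of p53 had 18 of 23 genes above 0 and a median of 0.19 (percentile 89.5), with DRAM1, a lysosomal regulator of autophagy, at 1.17 and TNFRSF10A, a death receptor, at 0.79. CDKN1A, the cell cycle inhibitor p21, gave 0.98 in a peak below the median signal, and like NDUFV3, ATP5PO and TFB1M it was named after its value was seen. RPS27L, the lowest of the 4 p53 targets below 0, gave −0.75 and was named in the same way. Stem cell and leukemia genes had a median of 0.09 (percentile 38.1) with CD34 and ARHGAP22 (1.19) in front, and the t(8;21) factors and partners one of 0.07 (percentile 21.0), with TCF4 at −0.63. The writers, erasers and readers of H4K20 methylation had 8 of 15 genes above 0 (median 0.04, percentile 25.5). The naming rule gave DTL and PHF2 (−0.90), which lies on the same part of chromosome 9 as PDCL. By the mean over a gene's peaks, KMT5B was highest (0.66 over 2 peaks) and PHF2 lowest (−0.50 over 4). Cytosolic ribosomal proteins gave 0.13 (68.5), splicing 0.17 (83.7), glycolysis 0.14 (60.1), oxidant defence 0.13 (49.3) and apoptosis 0.07 (35.0). Erythroid and megakaryocytic markers gave 0.05 (43.9), lymphoid markers 0.02 (32.4) and liver markers −0.19 (9.28). In all, 5 of 21 lists with at least 5 measured genes lay outside the central 95% of random lists. If the genes of a list varied independently of each other, 1.05 would. Genes of a list can differ together between any 2 libraries, and some lists share members such as DTL and BIRC5. The 2 numbers thus do not show an excess due to the conditions. Of 16 list medians above 0, 9 were at or below 0 with scaling to reads in peaks, which leaves the percentiles as they were.

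**Figure D2:**
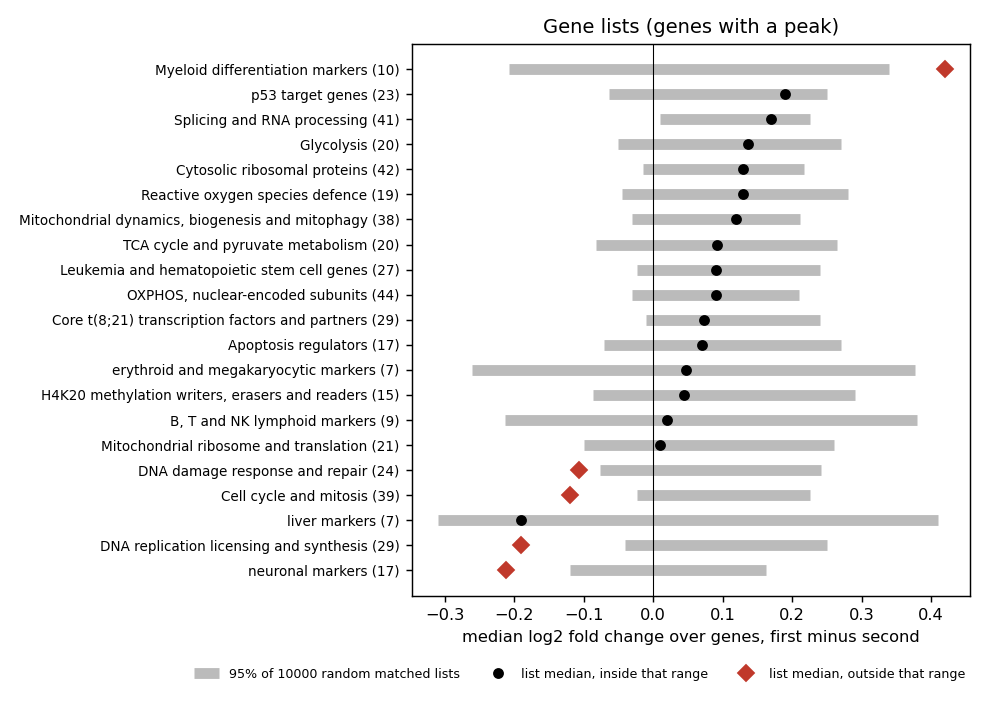
Median over genes of the mean peak log2 fold change (x axis, first-listed minus second-listed group) for each fixed gene list (y axis, number of measured genes in brackets), with grey bars for the central 95% of 10000 random matched lists. Replication (−0.19), cell cycle (−0.12), damage response (−0.11) and neuronal (−0.21) lists lie below their bars and the myeloid list (0.42) above.

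The lists also differed in how many of their genes had a peak at all, over both groups together. Matching was on gene length alone and not on gene activity. Without a control library, a peak may hold background cuts as well as the mark. A peak in promoter or body was present at 38.6% of 19970 protein-coding genes. Splicing genes carried a peak in 82.0% of cases (exact 95% interval 68.6 to 91.4), against 36.5% in lists matched on gene length, glycolysis genes in 80.0% (59.3 to 93.2) against 39.0%, and the t(8;21) factors and partners in 78.4% (61.8 to 90.2) against 45%. Cytosolic ribosomal protein genes did so in 56.0% (44.1 to 67.5) against 21.7%, and oxidative phosphorylation genes in 57.1% (45.4 to 68.4) against 29.2%. HOX genes carried a peak in 7.69% of cases (3 of 39), against 21% in matched lists (percentile 1.33). Of these HOXB7, on the same part of chromosome 17 as BIRC5, gave −0.43 and HOXC12 0.28. Replication-dependent histone genes did so in 6.78% (4 of 59), against 14.4%, which lay inside the central 95% of matched lists (percentile 3.88), and H2BC5 gave 0.61 and H2BC4 −0.58.

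Chromosomes 17, 9 and 2 were lower in the first-listed group than the rest. Their median log2 fold changes were −0.14, −0.085 and −0.05, while those of the other autosomes and X ran from 0.03 on chromosome 5 to 0.16 on chromosome 20. Chromosome 17 held 49 peaks that were lower in the first-listed group at an unadjusted p under 0.05 in the authors' deposited table and 6 that were higher (odds ratio for lower 3.09, interval 2.28 to 4.18). Chromosome 9 held 34 and 8 (2.79, 1.95 to 4.00), and chromosome 2 held 58 and 40 (2.48, 1.87 to 3.28). Chromosome 6, with a median of 0.06, held 49 lower and 56 higher peaks (odds ratio for lower 1.66, 1.23 to 2.24). Higher peaks exceeded their share on chromosomes 20 (30 peaks, odds ratio 1.74, 1.20 to 2.53), 8 (91 peaks, 1.51, 1.21 to 1.89) and 3 (93 peaks, 1.39, 1.12 to 1.73). With scaling to reads in peaks all medians move by −0.11, so that differences between chromosomes are kept while 16 of 23 medians, in place of 3, lie below 0.

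**Figure D3:**
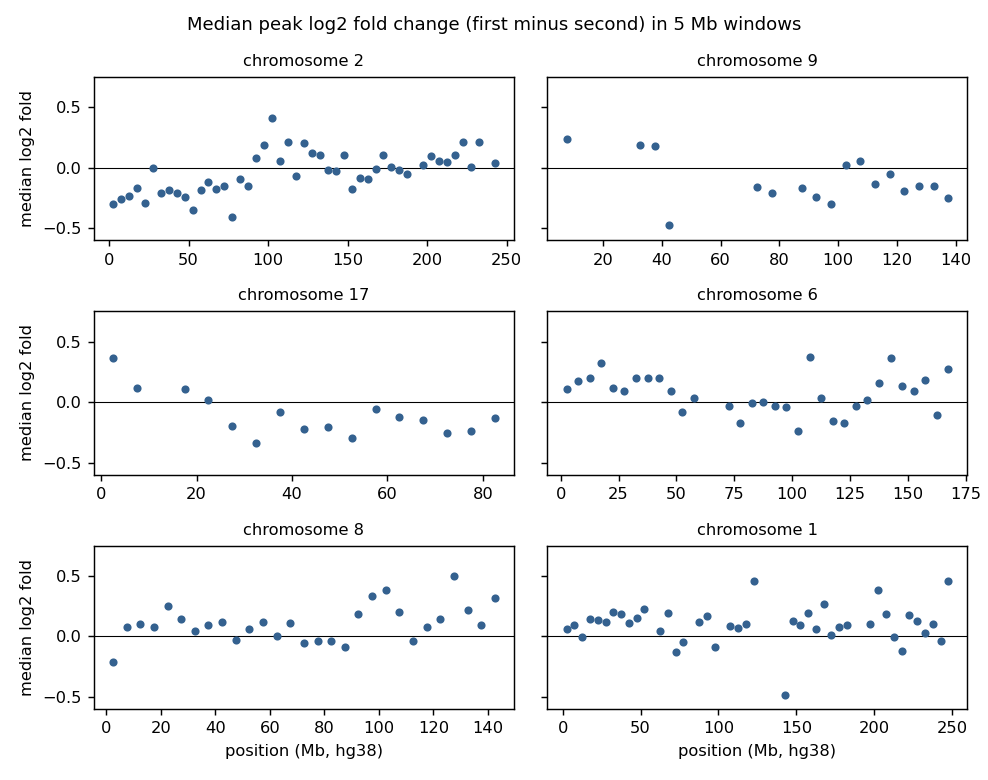
Median log2 fold change of peaks (y axis, first-listed minus second-listed group) in 5 Mb windows with at least 10 peaks along 6 chromosomes (x axis, position in Mb of hg38). Points of chromosome 2 lie mostly below 0 over its first part, those of chromosomes 9 and 17 over their later part, and the window of chromosome 8 that ends at 130 Mb has a median of 0.50.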

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

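The scaling, lowest-step and chromosome segment alternatives were chosen after seeing the data. The count of peaks at an adjusted p under 0.05 in the authors' deposited table stayed at 0 at 0.01, with a log2 fold change of at least 1 as well, with the Benjamini-Hochberg adjustment recomputed, without the lower quartile of signal and on chromosomes 1 to 22 and X. It was 1 at an adjusted p under 0.1, and 1292 at an unadjusted p under 0.05, as looser limits admit more. The median log2 fold change of 0.06 was 0.12 at or above the median signal, 0.08 weighted by peak width, 0.07 without lowest-step peaks, 0.09 without 2p, 9q and 17q, −0.054 scaled to reads in peaks and 0.003 without scaling. The 2 scaling values follow from the constant each subtracts, and for the others the cause was not tested. The promoter minus intergenic difference of 0.10 was 0.15 at or above the median signal and 0.13 without lowest-step peaks, the cause of which was not tested. Lists outside the random range numbered 3 in place of 5 with peaks of at least median signal, where 18 lists could be measured and the myeloid list could not. Of 122 list medians under alternatives, 119 kept their side of the range and 3 moved inside it. No paired analysis was possible because the table gives 1 value per group and none per library. For the same reason another tool, library-total scaling, other pseudocounts, leaving out replicates and the replicate block were not run. Depth limits single peaks, which held a median of 72 reads per column.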

Other observations

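All patterns and tests in this part were chosen after the values were seen. Some genes had values on 1 side of 0 in most or all of their peaks, with no test of the difference. Among 777 genes with at least 5 peaks above the lowest step, TRIO on chromosome 5 had all 36 peaks above 0, with a median log2 fold change of 0.81 and 13720 against 7637 reads. FAM107B (median 1.51, 5 peaks), GAB2 (1.03, 6 peaks), CDK17 (0.93, 8 peaks), DENND5A (0.79, 11 peaks) and ATP2C1 (0.73, 12 peaks) also stood high. At the other end, RBFOX3 had all 25 peaks below 0 (median −0.53, 4166 against 6182 reads), and DNMT1, the maintenance DNA methyltransferase, all 6 (median −0.48). The 5 Mb window of chromosome 8 that ends at 130 Mb had the highest median of the 193 windows with at least 50 peaks, 0.50 over 64 peaks. In it PVT1 (median 0.75 over 16 peaks by nearest gene), CYRIB (0.60 over 11) and TRIB1 (0.79 over 3) stood high, while the reads of the 2 peaks nearest to MYC, 633 against 578, gave a log2 ratio of 0.19 (median of the peaks 0.49). The first 45 Mb of chromosome 5 held 27.1 peaks per Mb, against 5.17 on the rest of that chromosome and 8.39 on the other autosomes, with a median log2 fold change of −0.02.

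The spread of peak log2 fold changes was set against counting error. The squared deviation from the common ratio averaged 3.52 times the binomial variance (95% bootstrap interval 3.44 to 3.61), where independent reads give 1 and reads counted in pairs 2. It was 1.70 in the lowest and 6.14 in the highest of 4 equal classes of signal. Separate libraries differ by more than counting error with or without a knockout, so these values decide nothing about its source.

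The factor between the columns bears on every direction given above. It was 1.0402, with the column of fewer reads in peaks scaled down. On the log2 scale the factor lay between 0.05686 and 0.05692, and the ratio of reads in peaks was 0.05709, a difference of 0.0002. A candidate explanation is that the ratio of reads in peaks was applied the wrong way round, which would raise all first-listed values by 0.11 against the second-listed ones. A factor from whole-library totals cannot be told apart from this, because the table holds no such totals.

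Peaks on 2p up to 90 Mb, on 9q from 40 Mb and on 17q from 25 Mb differed from peaks elsewhere by −0.29, −0.27 and −0.30, first-listed minus second-listed. The segments were picked for their low values, which by itself favours a negative difference. Against peaks of the same class and signal the difference was still −0.305 (−0.33 to −0.28). This argues only against annotation class and signal level as the whole cause. GC content and mappability of the peaks were not checked. In a search of 23 chromosomes for their best breakpoint, those of chromosomes 2, 9 and 17 lay at 86.1, 40.6 and 28.5 Mb, and 0 of 1000 shuffles of blocks of peaks gave as large a step, which argues against counting error and also held for chromosome 6 at 44.4 Mb (0.20 before, −0.01 after) and chromosome 8 at 92.0 Mb (0.06 and 0.22). Promoters, gene bodies and intergenic peaks were all lowered, the least by −0.26. The segments were picked for low values, so this gives no support to a difference in DNA copies between the cell pools. A regional change in the mark would lower all these classes as well. Promoters were lowered by more than intergenic peaks (−0.085, −0.14 to −0.04), but this gap cannot decide whether copies are the whole cause. The matched peaks elsewhere include regions with low values of their own, such as chromosome 6 from 100 to 105 Mb (median −0.24, 79.5% intergenic). A difference in DNA copies and an untested effect of the knockout on the mark both stay open. Effects of GC content, mappability and other technical differences between the libraries also stay open, because they were not tested. The columns hold no separate libraries, so differences between libraries that arise without a knockout cannot be set aside either.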
